A study of Mus musculus with 6 samples.

How the data were processed

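RNA was measured in 6 libraries of eosinophils cultured from the bone marrow of wild-type BALB/c mice, with 1 library for each of 6 groups. The groups were untreated cells, cells given IL-4 and cells given IL-33, each at 1 h and at 4 h. Total RNA was made into single-read Illumina libraries, per the labels' protocols. With 1 library per group, no difference has a replicate check and no p-value across genes was computed.

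The values analysed were FPKM (fragments scaled by transcript length and by library size), deposited by the authors for 28702 RefSeq transcripts in 4 tables, each holding 1 treated library and the untreated library of its time. Reads were aligned with TopHat 1.4.1 to build mm9 and transcripts were quantified with Cuffdiff 1.2.1, per the submitters' processing notes. Any trimming and the RefSeq release used were not given in the sources used here. The p-value and q-value columns of the authors' deposited tables come from a test on the reads of 2 libraries, which compares those libraries and not the conditions, and they were not used as tests of conditions. A further deposited list gave the authors' log2 fold changes and significance marks for 1593 genes. For genes with 1 transcript, its 4 columns of log2 fold changes equalled those of the table of the same name for 100%, within 0.01 log2. They equalled those of another table for at most 1.63%.

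The tables had been normalised separately. The untreated library of 1 h had values in the IL-33 table that were 0.945 times those in the IL-4 table, and the factor for 4 h was 0.947, with 100% of transcripts within 0.1% of that factor. Each treated library was therefore compared with the control column of its own table. IL-33 was set against IL-4 by the difference of the within-table log2 changes. The comparison of the untreated libraries of 4 h and 1 h used the control columns of the IL-4 tables and is a comparison across tables. Levels shown for untreated cells outside a comparison come from the same columns.

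The design had assumed values per gene, and the files held values per transcript. The transcripts of a symbol were summed, which gave 22548 symbols, of which 3869 had several transcripts and 232 lay at several loci. For symbols at several loci, the locus of highest total FPKM over the deposited tables was kept. Change was measured as log2((treated FPKM + 1) / (control FPKM + 1)), a scale that understates the change of genes with low values. Genes with FPKM of at least 1 in at least 1 of the 2 libraries were compared, and "higher" or "lower" means an absolute log2 change of at least 1. An FPKM of exactly 0 can be a failed estimate, so such a gene is described as listed at 0.

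The genes named were set by a rule fixed before the data were examined. It took the 15 genes with the largest rise and the 8 with the largest fall per comparison, among those past the rule of size with FPKM of at least 5 in the higher library, and 8 in each direction for IL-33 against IL-4. Predicted and small RNA symbols were passed over. Il4, Il13, Il6, Il5, Il1rl1, Il4ra, Il1b, Tnf and Csf2 were always named, and up to 4 members per gene list were given as examples. A few genes that the rule or a list would name are not reported here. The 24 gene lists were fixed at the same time. For each list, the members past the rule were counted and the median log2 change was placed among 10000 random lists of the same size, matched in 10 bins of mean level. These percentiles describe the 2 libraries compared and are not p-values. In all, 47 of the 120 list medians lay outside the central 95% of their random lists. Some genes stand in several lists.

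Overlaps between IL-33 and IL-4 share the untreated library. They are given beside the overlap of independent lists (n1 × n2 / N, with the genes compared in both) and beside 200 simulated pairs of unchanged libraries set against a shared control. Noise for the simulation was resampled from the difference between the untreated libraries of 4 h and 1 h, which also holds the effect of time. A second simulation, added after seeing the data, took the noise from IL-4 1 h against control 1 h, which also holds the effect of IL-4.

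The steps were tested on simulated data with 200 changed genes per comparison. Of genes changed by 1.5 log2, the steps recovered 97% for IL-4 1 h, 98% for IL-4 4 h, 100% for IL-33 1 h, 99% for IL-33 4 h and 97% for the untreated libraries. Of genes changed by 3 log2, at least 99% were recovered in each comparison. Unchanged genes past the rule were 0.768%, 0.534%, 0.605%, 0.722% and 0.561% in the same order. Noise came from the untreated libraries in each case, scaled to the share of 1 library and added to the treated side only. Small RNA genes and genes under FPKM 1 in the control were left out. These are thus not error rates of the real comparisons. There, 10 and 2 of 10493 such larger genes were past the rule for IL-4 1 h, and 49 and 128 of 10678 for the untreated libraries. Of 200 lists without a change, 6%, 7%, 4.5%, 4.5% and 4% lay outside the central 95%.

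Depth was not given as read numbers. For genes with very low values, the FPKM of 1 library over that of its control fell most often on 1 ratio, as whole reads divided by length and depth would give, and this ratio gave the relative depths stated with the results. It was shared by 18.7% to 25.6% of the low genes, within 0.5%, so the depths are estimates. Read counts could not be recovered from the FPKM and no counting intervals are given.

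Coordinates are those of the deposited tables, on mm9. Starts were taken to count from 0 there and 1 was added, because the length of microRNA loci then equalled that in the reference for 37.6% of them, compared with 1.12% if starts counted from 1. Most microRNA lengths equalled neither, so printed starts may be off by 1. The reference annotation used here is of another mouse build, GRCm38, and served only for gene names and for the class of small RNA genes. It held 22342 (99.1%) of the symbols. The small RNA class, with 731 genes, took in microRNAs, small nucleolar and small nuclear RNAs, whose FPKM rest on very short transcripts. The alternatives tried were another pseudocount, other filters on low values, centring on the median, the control of the other time and the authors' calls. Those added after seeing the data were leaving out the small RNA genes, taking the highest transcript in place of the sum, leaving out genes with failed or low-data transcripts, and leaving out heart muscle genes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.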

Results

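The data were RNA-seq profiles of mouse eosinophils, granulocytes that take part in allergic inflammation and in the defence against worms. Low-density bone marrow cells of BALB/c mice were grown for 14 days, with stem cell factor and FLT3 ligand at 100 ng/ml for the first 4 days and IL-5 at 10 ng/ml from then on. The cells then received 10 ng/ml of IL-33 or IL-4, or no cytokine, for 1 h or 4 h. IL-33 is an IL-1 family cytokine that signals through its receptor ST2 (Il1rl1) to NF-kB, and IL-4 signals through STAT6. The series asked which transcripts IL-33 raises in eosinophils, and which part of this response runs through IL-4 that the cells themselves release. Each of the 6 groups had 1 library, so differences between groups could not be set against a spread between replicates, and no p-values are given.

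Total FPKM was 739248 and 728873 in the control libraries of 1 h and 4 h, 724175 and 744894 with IL-4, and 752634 and 762011 with IL-33. Genes with FPKM of at least 1 numbered 10458 and 10614 in the controls, 10445 and 10682 with IL-4, and 10387 and 10456 with IL-33. Depth relative to the control of the same time was estimated as 0.975 for IL-4 1 h, 1.24 for IL-4 4 h, 1.16 for IL-33 1 h and 1.89 for IL-33 4 h. IL-33 1 h and both treated libraries of 4 h were thus deeper than their controls, and low values were less precise in the control of 4 h than in its treated partners. Log2 changes are of FPKM + 1, which understates the change of genes with low values.

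The libraries carried the transcripts of eosinophils at high levels. Prg2, the major basic protein of eosinophil granules, was the most abundant gene in every library and held 5.52% to 7.05% of the total FPKM. Among the untreated cells of 4 h, Epx (eosinophil peroxidase) stood at 2027 FPKM, Ccr3 (the eotaxin receptor) at 437, Siglec5, which encodes the protein Siglec-F, at 245 and Il5ra (the IL-5 receptor chain) at 26.0. Transcripts known from other blood cells were also present in these libraries. The neutrophil and monocyte gene S100a8 stood at 3005 FPKM in the same library, the monocyte and macrophage gene Csf1r at 97.8, the mast cell and basophil protease gene Cpa3 at 97.8 and the basophil protease gene Mcpt8 at 91.9.

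IL-33 for 1 h was compared with no cytokine to find the early response. Members of the lists of NF-kB targets, cytokines and chemokines were among the genes with the largest rises. Nfkbiz, a nuclear regulator of NF-kB target genes, stood at 4.30 FPKM without cytokine and 366 with IL-33 (log2 change 6.11). The neutrophil chemokine gene Cxcl2 went from 14.3 to 699 FPKM (5.51), Tnf from 8.59 to 339 (5.15), Il6 from 7.31 to 217 (4.71) and the early activation marker Cd69 from 2.78 to 142 (5.24). Nfkbia, which encodes the inhibitor IkB-alpha, reached 1083 FPKM from 68.7. In the mm9 build, Il6 (NM_031168) lies on chromosome 5 at 30339701 to 30346508, Tnf (NM_013693) on chromosome 17 at 35336336 to 35338941, and Cxcl2 (NM_009140) on chromosome 5 at 91332925 to 91334964. Nfkbiz, with several transcripts, lies on chromosome 16 at 55811490 to 55838754.

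Among the other genes with the largest rises at 1 h, Tnfaip3, the ubiquitin-editing enzyme A20, went from 12.4 to 280.2 FPKM, and Zc3h12a, a ribonuclease that degrades cytokine mRNA, from 6.71 to 172. Irg1, the enzyme that makes itaconate, stood at 25.9 and 551 FPKM, the adenosine receptor gene Adora2b at 5.74 and 132, and the adhesion molecule gene Icam1 at 9.40 and 126. Ccrl2, an atypical receptor that binds chemerin, stood at 59.3 and 666 FPKM. Cxcl10, a chemokine gene known from interferon responses, stood at 1.80 and 68.0, while Cdc42ep2, a Cdc42 effector, went from 0.661 to 45.5 and Ralgds, a Ral exchange factor, from 3.57 to 55.5. The falls were smaller. B3gnt7, a glycosyltransferase gene, fell by 2.00 on the log2 scale, from 7.98 to 1.25 FPKM, and the log2 changes of Frat1 and Frat2, which bind the kinase GSK3, were -1.75 and -1.65. The log2 changes of Tnfaip8l2, an inhibitor of immune activation, Klhl21, the lysophosphatidic acid receptor gene Lpar6, Gpr146 and Ahr, the aryl hydrocarbon receptor, were -1.58, -1.58, -1.57, -1.52 and -1.51.

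By gene list, 25 of 41 measured NF-kB targets were higher with IL-33 at 1 h, 16 were neither higher nor lower, and the median log2 change was 1.88 (percentile 100 of random lists). Of 37 immediate early genes, 16 were higher, such as the nuclear receptor gene Nr4a3 (2.03 to 31.6 FPKM) and Gem (0.742 to 8.46), with a median of 0.87 (percentile 100). Higher members numbered 8 of 25 cytokines and growth factors, with Il1b (31.4 to 216) and Il13 (2.01 to 17.3) among them, and 8 of 22 chemokines, such as Cxcl3 (43.6 to 276) and Cxcl1 (0.361 to 6.60). Among 48 adhesion and activation genes, 8 were higher, including the lectin gene Clec4e (68.1 to 603) and the scavenger receptor gene Olr1 (64.1 to 281). Of 29 apoptosis and survival genes, 11 were higher, with both survival genes such as Birc3 (67.1 to 334) and the death-promoting Bcl2l11 (35.2 to 152). The Bcl2a1 copies in this list may share reads, so their separate values are uncertain. No member of these 6 lists was lower. Of 29 JAK-STAT feedback genes, 5 were higher, among them Cish (9.48 to 101) and the kinase gene Pim1 (64.7 to 324).

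In total, 251 genes were higher and 71 lower of 10616 compared. Small RNA genes made up 44 and 41 of these, which left 207 and 30. Of the markers of other blood cells, none of 10 mast cell and basophil markers (median 0.05, percentile 81.5) and none of 20 neutrophil markers (0.09, percentile 97.0) was past the rule, and 1 of 24 monocyte, macrophage and dendritic cell markers, Cd14, was higher (86.5 to 178). None of 11 lymphoid and innate lymphoid markers was past the rule, but their median of 0.21 stood at percentile 99.8, and 9 erythroid and megakaryocyte markers had a median of -0.13 with none past the rule. Against the control of 4 h in place of 1 h, 433 genes were higher and 345 lower, and with a pseudocount of 0.1 the lower genes numbered 127.

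IL-33 for 4 h was compared with the control of 4 h to find the later response. Cytokine and chemokine genes were among those with the largest rises. Cxcl2 went from 5.39 to 516 FPKM (log2 change 6.34), Il6 from 4.75 to 336 (5.87), Il1b from 5.95 to 243 (5.13) and Tnf from 7.35 to 177 (4.41). Il13, the type 2 cytokine of airway mucus and worm expulsion, went from 0.971 to 46.8 (4.60), above its 17.3 FPKM with IL-33 at 1 h in a separately normalised table. The chemokine genes Cxcl3 and Ccl3 reached 282 and 2827 FPKM, from 9.32 and 158. Il13 (NM_008355) lies on chromosome 11 of mm9 at 53444825 to 53448204.

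Beyond the cytokines, Smpdl3b, a lipid-modifying phosphodiesterase gene, went from 0.918 to 83.0 FPKM and Ptgs2, the inducible cyclooxygenase, from 0.432 to 45.4. The survival kinase gene Pim2 stood at 4.33 and 165, the retrotransposon-derived Peg10 at 3.65 and 151, Irg1 at 6.07 and 155, Clec4e at 19.4 and 434 and Treml4, a receptor known to bind dead cells, at 1.16 and 38.8. Pisd-ps1 also stood among the largest rises (0.00249 to 22.4), but it is a pseudogene copy that may share reads with Pisd and is uncertain. Csf2, which encodes GM-CSF, was listed at 0 in the control and at 3.30 FPKM with IL-33. The genes with the largest falls were Cpeb1, a regulator of mRNA polyadenylation (16.6 to 3.68), the PI3-kinase inhibitor gene Pik3ip1 (23.1 to 5.43), Fbxo31 (11.7 to 2.41), Cdh17 (6.16 to 1.41), Miox (18.0 to 5.46), Mns1 (23.4 to 7.42), Rogdi (63.1 to 21.2) and Tmem86a (16.2 to 4.97).

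NF-kB targets were higher in 28 of 42 cases at 4 h, with a median of 2.14 (percentile 100), for example Tnfrsf9 (0.715 to 27.0 FPKM) and Bcl3 (6.89 to 91.0). Chemokines were higher in 14 of 22 cases (median 1.44, percentile 100), and cytokines and growth factors in 10 of 27, with 1 lower. Adhesion and activation genes were higher in 16 of 49 cases, such as Cd69 (1.33 to 37.8), Icam1 (13.9 to 101) and the inhibitory receptor gene Siglece (2.57 to 27.3). Apoptosis and survival genes were higher in 12 of 30, including the death receptor gene Fas (15.2 to 144), and immediate early genes in 11 of 34. Of 29 JAK-STAT feedback genes 8 were higher, among them Cish (11.2 to 67.7), Socs3 (1.37 to 11.3) and Socs1 (3.89 to 18.6). Cytokine and chemokine receptors were higher in 7 of 47 cases, such as the shared receptor chain gene Il2rg (38.8 to 182), and 1 was lower.

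Of 30 members of the IL-4/STAT6 response list, 11 were higher with IL-33 at 4 h and 19 were not past the rule (median 0.52, percentile 100). They included Arg1, the arginase of alternatively activated macrophages (1.24 to 9.43), Batf3 (7.66 to 36.4), Egr2 (2.84 to 25.1) and Cish. At 1 h, 4 of 31 were higher with IL-33 (median 0.10, percentile 99.6), namely Cish, Pim1, Tgm2 (39.4 to 121) and Egr2 (12.4 to 31.3). Cish and Pim1 are also known targets of STAT5, and Egr2 is also an immediate early gene.

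Of 36 eosinophil identity genes, 1 was higher, the transcription factor gene Cebpb (87.9 to 314 FPKM), and 2 were lower, Hrh4 (1.55 to 0.121) and Ltc4s (2.38 to 0.671), with a median of -0.02 (percentile 32.6). Cell cycle genes had a median of -0.30 (percentile 0) with none of 30 past the rule, the replication gene Mcm6 standing at 20.3 and 11.1 FPKM. Mast cell and basophil markers had a median of -0.16 (percentile 9.70), with 1 of 10 higher, Mitf (4.76 to 10.99). Neutrophil markers had a median of -0.22 (percentile 0.280), with 1 of 20 higher, Fpr1 (8.37 to 30.4). Monocyte, macrophage and dendritic cell markers had 4 of 24 higher, namely Cd14 (44.6 to 207), Batf3, Csf1r (92.6 to 217) and Mrc1 (4.85 to 10.8), and a median of -0.10 (percentile 10.1).

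In total, 448 genes were higher and 149 lower of 10803 compared, or 396 and 113 without the small RNA genes. Of the genes other than small RNA genes, 133 were higher and 7 lower at both 1 h and 4 h, against 7.01 and 0.312 for independent lists. Among the 133 were Nfkbiz, Tnfaip3, Il6, Il13, Tnf and Cxcl2. With a pseudocount of 0.1, the genes lower at 4 h numbered 324.

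**Figure D1:**
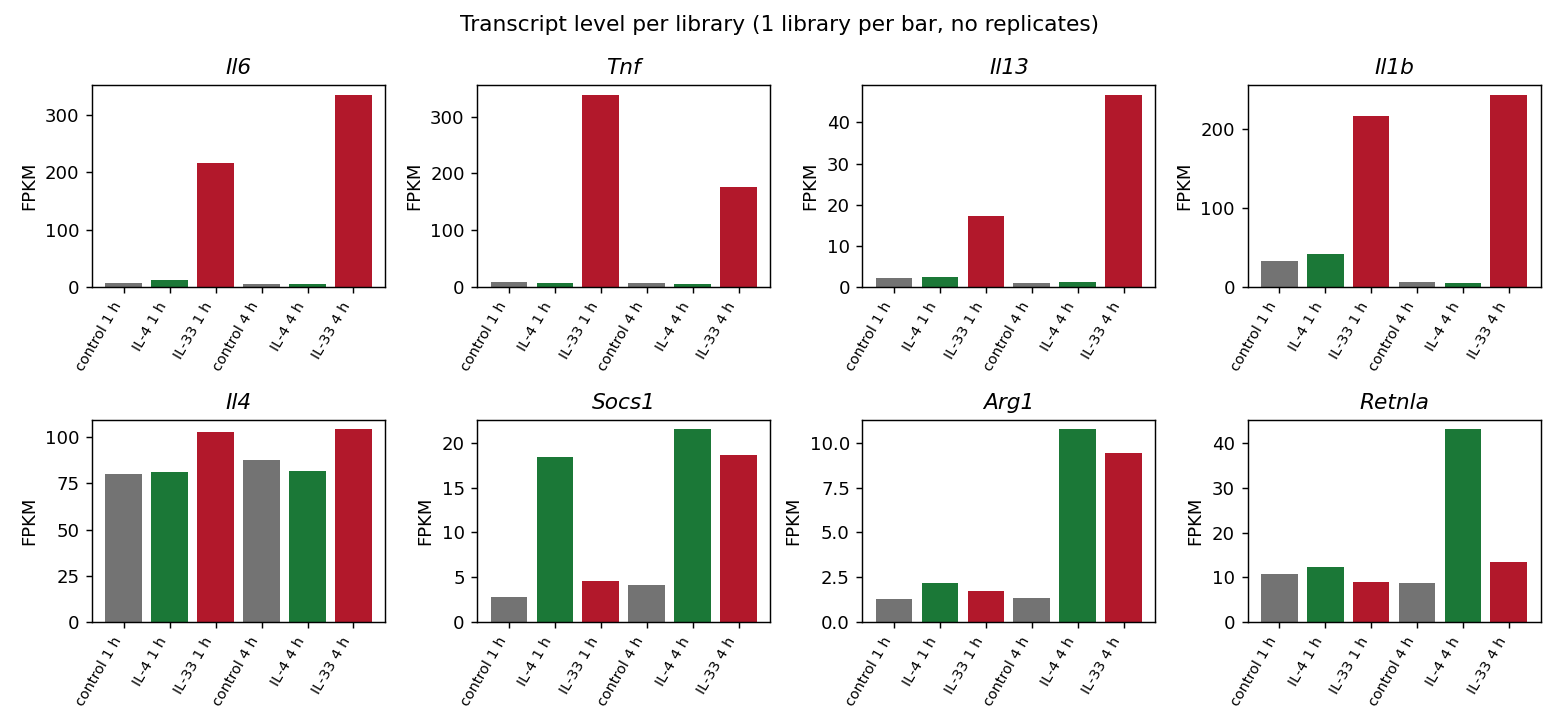
Transcript level (FPKM, linear axes from 0) of 8 genes in the 6 libraries, 1 library per bar, with controls in grey, IL-4 in green and IL-33 in red. Il6, Tnf, Il13 and Il1b stood highest with IL-33, Retnla with IL-4 at 4 h (43.1 FPKM), and Il4 lay between 80.3 and 104 FPKM in all 6 libraries; the IL-4 and IL-33 values come from separately normalised tables, with controls from the IL-4 tables.

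IL-4 for 1 h was compared with no cytokine as the reference for a direct IL-4 response. Few genes changed. Socs1, a suppressor of cytokine signalling that STAT6 induces, went from 2.80 to 18.4 FPKM (log2 change 2.35), and Cish, of the same family, from 10.0 to 25.7 (1.28). The monocyte chemokine genes Ccl7 and Ccl2 stood at 20.4 and 5.75 FPKM without cytokine and at 60.7 and 17.6 with IL-4. Socs1 (NM_009896) lies on chromosome 16 of mm9 at 10783902 to 10785629, and Ccl7 (NM_013654) on chromosome 11 at 81859214 to 81861025.

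Col1a1, Col1a2 and Sparc were also higher with IL-4 at 1 h, singled out here after their values were seen. Col1a1 stood at 0.437 FPKM in the control and 2.93 with IL-4, Col1a2 at 0.923 and 3.20, and Sparc at 1.31 and 4.08. With IL-33 at 1 h the same genes stood at 1.58, 2.33 and 2.36 FPKM in a separately normalised table. The ribosomal protein gene Rps27 fell by 4.88 on the log2 scale, from 174 to 4.94 FPKM, and is uncertain because similar copies may share its reads. The IL-4/STAT6 list had 2 of 30 members higher (median 0.12, percentile 100) and the chemokines 3 of 18, Ccl7, Ccl2 and Ccl12 (0.572 to 2.20). No NF-kB target of 39 and no immediate early gene of 37 was past the rule, with medians of 0.02 (percentile 99.4) and 0.05 (percentile 99.98). The 5 lists of markers of other blood cells had no member past the rule, and the mast cell and basophil markers had a median of 0.04 (percentile 98).

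Of 10628 genes compared with IL-4 at 1 h, 50 were higher and 38 lower, but 40 and 36 of these were small RNA genes, which left 10 and 2. Against the control of 4 h, the counts over all genes were 178 and 117.

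IL-4 for 4 h was compared with the control of 4 h as the later reference. Members of the IL-4/STAT6 list were among the genes with the largest rises. Arg1 went from 1.31 to 10.8 FPKM (log2 change 2.35) and Retnla, which encodes the secreted protein RELM-alpha, from 8.64 to 43.1 (2.20). Socs1 stood at 4.11 and 21.5 FPKM, Ccl7 at 26.9 and 130.1, Ccl2 at 7.04 and 25.9 and the arginine transporter gene Slc7a2 at 2.53 and 9.95. Il6, Tnf, Il1b and Il13 were not past the rule with IL-4 at either time. Arg1 (NM_007482) lies on chromosome 10 of mm9 at 24635013 to 24647276 and Retnla (NM_020509) on chromosome 16 at 48842665 to 48844574.

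Further rises at 4 h were seen for Tmem26 (0.715 to 5.34 FPKM), the mitochondrial assembly factor gene Pet117 (1.57 to 7.19), the transcription factor genes Tcfec (1.06 to 5.51) and Egr2 (3.00 to 10.5), the endocytic adaptor gene Dab2 (7.51 to 25.02), the GTPase gene Gimap3 (4.33 to 14.95), the protease inhibitor gene Serpina3g (2.38 to 8.19) and the proteoglycan gene Sdc4 (9.27 to 26.1). Pisd-ps1 (0.00262 to 7.65) and Rpl26, which was listed at 0 with IL-4 and at 12.9 FPKM in the control, may share reads with similar copies and are uncertain.

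The IL-4/STAT6 list had 10 of 32 members higher and 22 not past the rule at 4 h, with a median of 0.65 (percentile 100). Immediate early genes had 3 of 33 higher, Egr2, Hbegf (0.236 to 2.38) and Myc (2.34 to 6.001), and no NF-kB target of 39 was past the rule (median 0.01, percentile 42.5). Chemokines had 2 of 19 higher and JAK-STAT feedback genes 2 of 29, Socs1 and Pim2 (4.58 to 11.2). Of 25 monocyte, macrophage and dendritic cell markers 2 were higher, Mrc1 (5.12 to 15.1) and Batf3 (8.09 to 18.6), with a list median of -0.01 (percentile 9.63). Mrc1 and Batf3 also stand in the IL-4/STAT6 list.

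Of 10833 genes, 70 were higher and 38 lower with IL-4 at 4 h, or 32 and 1 without the small RNA genes. Genes other than small RNA genes that were higher at both times numbered 3, Ccl2, Ccl7 and Socs1, against 0.0169 for independent lists. With a pseudocount of 0.1, 118 genes were higher and 65 lower, and against the control of 1 h 128 and 152.

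IL-33 was set against IL-4 at each time to find which transcripts differed between the cytokines. At 1 h, 252 genes were higher and 71 lower with IL-33 than with IL-4 by the difference of the log2 changes, or 210 and 33 without the small RNA genes. At 4 h the counts were 402 and 117, or 358 and 89. With a pseudocount of 0.1, 110 genes were lower with IL-33 than with IL-4 at 1 h and 290.0 at 4 h. The genes with the largest differences included Nfkbiz (6.01), Tnf (5.42) and Cxcl2 (5.33) at 1 h and Cxcl2 (6.71), Il6 (5.57), Smpdl3b (5.50) and Il1b (5.37) at 4 h. Genes lower with IL-33 than with IL-4 included Socs1 at 1 h, at 4.54 FPKM with IL-33 and 18.4 with IL-4 (-1.75), as well as B3gnt7 (-2.38) and Ahr (-1.57). At 4 h they included Retnla, at 13.4 FPKM with IL-33 and 43.1 with IL-4 (-1.55), the endothelial lipase gene Lipg (-1.69), the E-cadherin gene Cdh1 (-1.57), Pi16 (-1.54), Fbxo31 (-1.81), Pik3ip1 (-1.78), Cpeb1 (-1.74) and Mns1 (-1.71).

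At 4 h, 21 genes other than small RNA genes were higher with both cytokines, among 32 higher with IL-4. They were Arg1, Batf3, Ccl2, Ccl7, Dab2, Egr2, Fchsd2, Hbegf, Mrc1, Myc, Pet117, Pgf, Pim2, Pisd-ps1, Sdc4, Serpina3g, Slc7a2, Socs1, Tcfec, Tgtp1 and Tmem26, of which Pisd-ps1 and Tgtp1 are uncertain because they may share reads with similar copies, which was not tested here. The log2 changes with IL-4 and with IL-33 were 2.35 and 2.22 for Arg1, 2.23 and 2.19 for Ccl7, 2.14 and 2.00 for Socs1, and 1.66 and 1.76 for Tcfec. They were 1.13 and 4.96 for Pim2, 1.44 and 3.15 for Serpina3g, and 1.52 and 2.76 for Egr2. Retnla (2.20 and 0.65) and Lipg (1.34 and -0.35) were past the rule with IL-4 and not with IL-33. At 1 h, 2 genes were higher with both, Ccl7 and Cish, of 10 higher with IL-4. The remaining genes had log2 changes above 0 with IL-33 at 1 h but under the rule, from 0.34 for Hist2h4 to 0.97 for Ccl2, with Socs1 at 0.60. These genes were chosen against the control of 1 h, which the IL-33 comparison also uses. A low value there alone would raise both changes. Hist2h4 is uncertain because similar copies may share its reads.

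The overlap of 21 genes at 4 h stood beside 0.892 for independent lists. Simulated unchanged libraries with a shared control gave 31.8 genes on average (200 sets, highest 50) with noise from the untreated libraries of the 2 times, and 2.44 (highest 8) with noise from IL-4 1 h. At 1 h the overlap of 2 genes stood beside 0.148, and over all genes the overlaps were 17 higher and 28 lower at 1 h (0.566 and 0.257 for independent lists, and 66.9 and 67.5 simulated) and 46 and 24 at 4 h (2.03 and 0.531, and the same simulated values). With noise from IL-4 1 h the simulated values over all genes were 35.6 and 36.2. The overlaps at 1 h thus did not exceed the mean of either simulation, nor did those of lower genes at 4 h. With noise from IL-4 1 h, the 21 genes higher at 4 h without the small RNA genes lay above the highest simulated value, while the 46 over all genes lay above the mean but below the highest of 56. Neither exceeded the mean of the simulation with noise from the untreated libraries, which decides little. The noise from IL-4 1 h comes from libraries of 1 h near equal in depth (0.975). At 4 h the shared control was shallower than its partners (1.24 for IL-4 and 1.89 for IL-33). Noise shared through the control of 4 h may thus be larger than simulated. An overlap cannot be larger than the number of genes changed with IL-4. Those were 50 higher and 38 lower at 1 h, and 70 and 38 at 4 h. Without the small RNA genes they were 10 and 2 at 1 h, and 32 and 1 at 4 h. The means of the simulation with noise from the untreated libraries could thus not be exceeded at 1 h or by lower genes at 4 h, and barely by higher genes at 4 h. With noise from IL-4 1 h, the mean of 2.725 lower genes without the small RNA genes could not be exceeded at either time. Over all genes, lower genes could barely exceed its mean of 36.2. At 1 h this noise is the change with IL-4 that the overlap itself uses, so the comparison at 1 h decides little. The single control library could not be split. Across genes, which are not independent replicates, the log2 changes with IL-33 and IL-4 correlated with r = 0.433 at 1 h and 0.468 at 4 h, and with 0.279 and 0.264 without the small RNA genes. Unchanged libraries gave 0.498 over all genes and 0.499 without the small RNA genes. Equal noise in each simulated library and a shared control fix this value whatever the data. A lower observed correlation therefore says nothing for or against a shared response. Over all genes the covariances were 0.142 and 0.180, beside 0.206 for the simulated libraries and 0.128 with noise from IL-4 1 h. Without the small RNA genes they were 0.0160 and 0.0256, beside simulated values of 0.0704 and, with noise from IL-4 1 h, 0.0105.

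**Figure D2:**
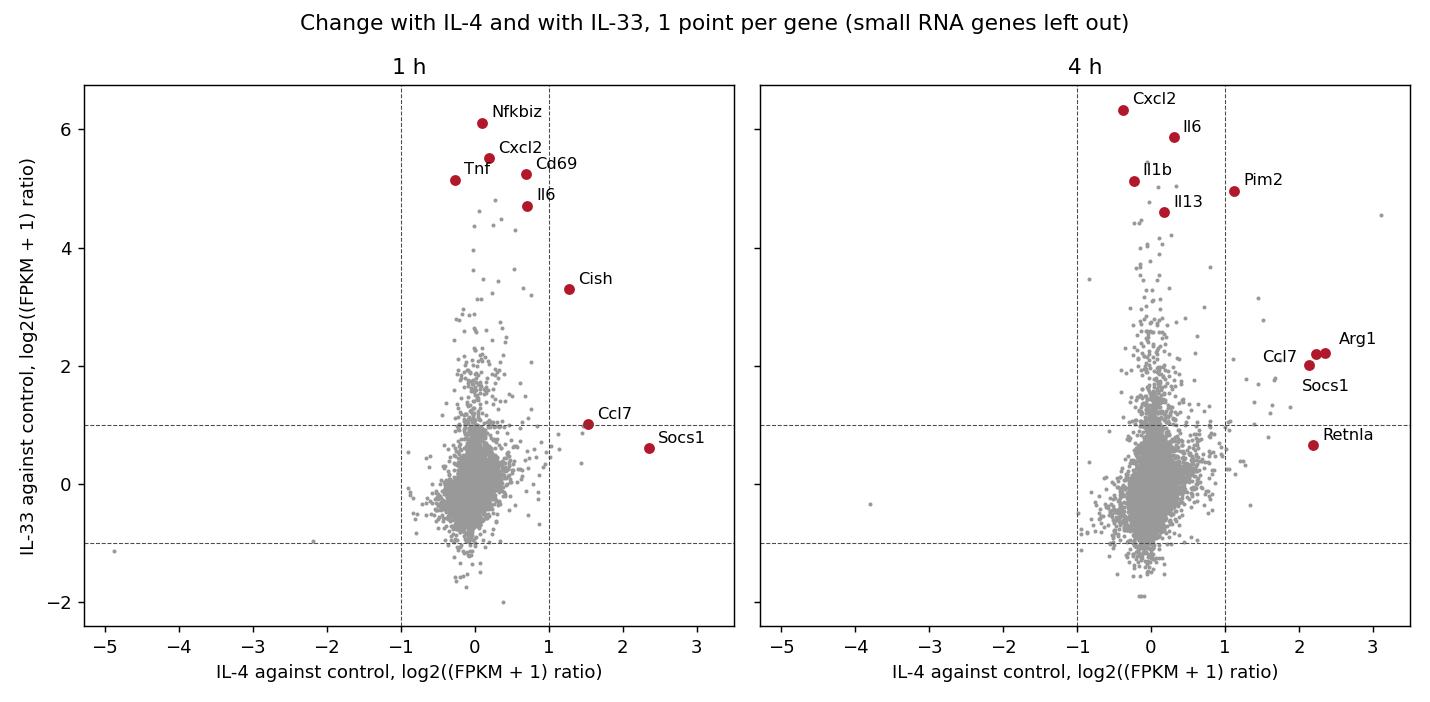
Log2 change of FPKM + 1 with IL-4 (x axis) and with IL-33 (y axis) against the control of the same time, at 1 h and 4 h, with 1 point per gene, small RNA genes left out and dashed lines at a log2 change of 1 and -1. At 4 h the points of Arg1, Ccl7 and Socs1 lie past the rule on both axes, Retnla only on the IL-4 axis among the genes labelled, and Cxcl2, Il6, Il1b and Il13 only on the IL-33 axis.

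The cytokine and receptor genes chosen in advance describe what could link IL-33 to IL-4. Il4 itself was present without cytokine, at 80.3 FPKM at 1 h and 87.4 at 4 h, and its log2 changes were 0.44 and 0.33 with IL-33 and 0.02 and -0.09 with IL-4, none of them past the rule. Il4 lies on chromosome 11 of mm9 at 53425963 to 53432167. Il4ra, the receptor chain for IL-4, had log2 changes of 0.20 and 0.57 with IL-33, and the IL-33 receptor gene Il1rl1 -0.25 at 1 h and 0.68 at 4 h, from 63.9 to 103 FPKM. Il5 was listed at 0 in 5 libraries and at 0.0242 FPKM with IL-33 at 4 h.

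The untreated libraries of 4 h and 1 h were compared to see what differed without a cytokine. Time in culture and library cannot be separated in this comparison. Egr3, an immediate early transcription factor, went from 75.7 to 3.39 FPKM (log2 change -4.13). Of 35 immediate early genes 9 were lower, 26 were not past the rule and none was higher (median -0.51, percentile 0), such as Fosb (9.94 to 0.269), Egr1 (33.9 to 5.79) and Nr4a1 (32.3 to 5.96). Chemokines had 4 of 18 lower, such as Ccl4 (140.2 to 28.4), and Il1b went from 33.3 to 6.29. Interferon response genes had 8 of 32 lower (median -0.49, percentile 0), including Isg15 (50.9 to 18.4) and Rsad2 (18.5 to 6.99). Cholesterol synthesis genes moved the other way, with 3 of 23 higher and a median of 0.63 (percentile 100), namely Lss (5.79 to 16.6), Fdft1 (13.6 to 34.1) and Sqle (18.8 to 44.3).

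Other genes higher at 4 h than at 1 h were Qpct (1.65 to 7.09), Acat2 (5.47 to 16.4) and the transcription factor gene Gfi1 (1.57 to 5.82). The integrin gene Itgax (14.0 to 34.9), the urokinase gene Plau (14.7 to 35.5) and Mns1 (9.75 to 24.7) were also higher. So were Tifab (3.56 to 9.76), Aacs (18.9 to 45.6), Zfyve21 (6.90 to 17.0) and Tob1 (23.3 to 53.8). Itgax is a marker of macrophages and dendritic cells. Heart muscle genes were among the named genes with the largest falls. Mb, the oxygen store of muscle, stood at 30.5 FPKM at 1 h and was listed at 0 at 4 h, the ventricular myosin light chain gene Myl2 at 33.1 and 0.150, and Actc1 at 30.4 and 0.812. Myh6 (15.4) and Tnnt2 (15.1) were listed at 0 at 4 h. These genes were also present in the libraries of IL-4 and IL-33 at 1 h, where Myh6 stood at 11.6 and 11.6. Rps27, Rpl26 and Pisd-ps1 also differed between the untreated libraries and are uncertain because of their copies.

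In total, 95 genes were higher and 169 lower at 4 h, or 49 and 128 without the small RNA genes. With a pseudocount of 0.1 the counts over all genes were 233 and 226, so the excess of lower genes was lost. The 2 libraries stand in separately normalised tables, with a median shift of 0.08 log2, and library and time cannot be separated. Of the genes higher with IL-33 and other than small RNA genes, 29 at 1 h and 34 at 4 h were among those lower in untreated cells at 4 h than at 1 h. Of the genes lower with IL-33 at 4 h, 13 were among those higher in untreated cells at 4 h. The control of 4 h enters both comparisons with opposite sign, so a low or high value there alone would add genes to the 34 and the 13. The shared control of 1 h works against the 29. No overlap of unchanged libraries was computed for these counts.

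**Figure D3:**
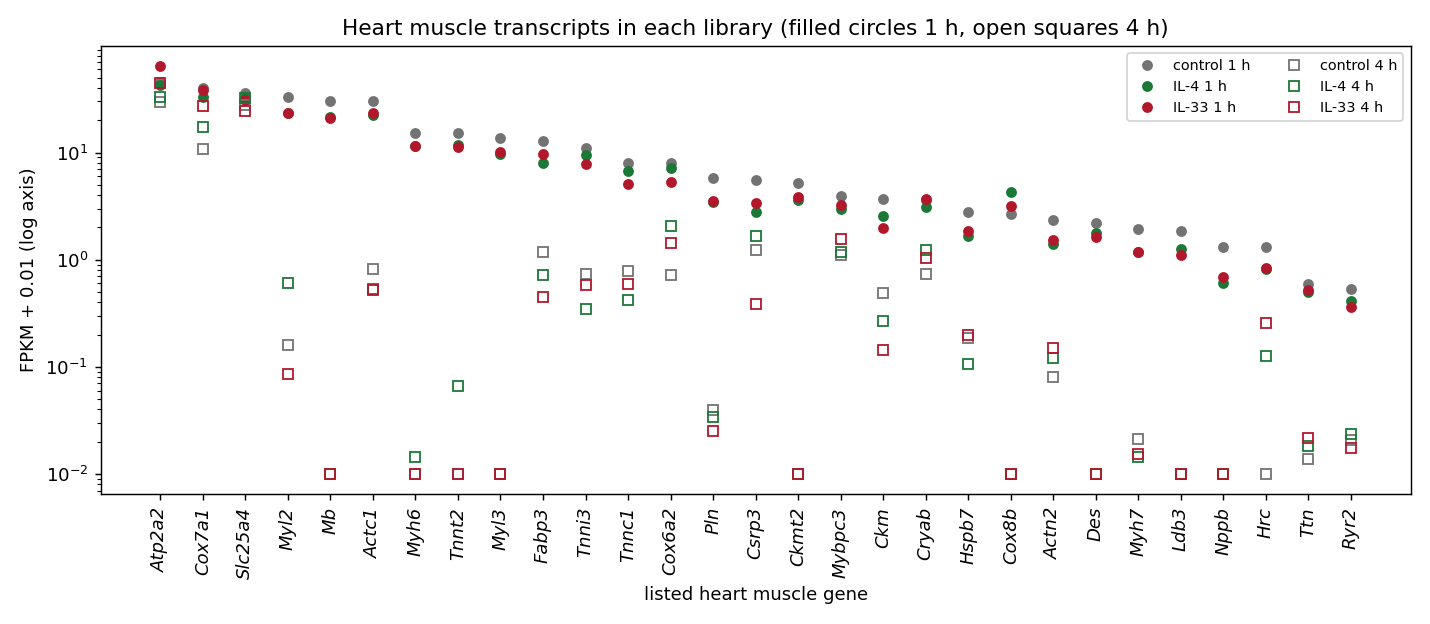
Level of 29 heart muscle genes, listed after the data were examined (FPKM + 0.01, log axis) in each of the 6 libraries, with filled circles for 1 h and open squares for 4 h, controls in grey, IL-4 in green and IL-33 in red. For 27 of the 29 genes, all 3 libraries of 1 h stood above all 3 libraries of 4 h; the values come from separately normalised tables.

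The authors' deposited table called more transcripts as changed than the rule of size. For IL-4 at 1 h the authors' deposited table marked 1770 transcripts of 1284 genes (822 higher and 948 lower), and for IL-4 at 4 h 1758 transcripts of 1287 genes (988 and 770). For IL-33 the authors' deposited table marked 1380 transcripts of 1190 genes at 1 h (785 and 595) and 1205 transcripts of 1064 genes at 4 h (785 and 420). Genes marked in the authors' deposited table and also past the rule of size numbered 9 and 29 for IL-4 and 231 and 476 for IL-33. Genes with several transcripts were 77.3% and 73.3% of those marked for IL-4 and 58.7% and 51.2% of those marked for IL-33 in the authors' deposited table, compared with 21.2% to 21.4% of the genes tested there. For 389 genes with IL-4 at 1 h, the authors' deposited table marked transcripts in both directions. The authors' list of regulated genes marked fewer genes. It had 246 higher and 402 lower for IL-4 at 1 h, and 400 and 238 for IL-4 at 4 h. For IL-33 it had 399 and 250 at 1 h, and 427 and 170 at 4 h. The calls of both kinds compare 2 libraries each, not the conditions.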

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

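The pseudocount, the filters on low values, centring, the control of the other time and the authors' calls were planned, and the other alternatives below were chosen after seeing the data. Of 201 recomputed values, 148 stayed within 1.5 times the main count or near the main correlation and 53 moved. Only a correlation could count as reversed, by a change of sign, and 0 did. The balance of higher and lower genes was not part of these labels and turned in some settings. For IL-4 4 h, 70 and 38 became 128 and 152 against the control of 1 h. For IL-4 1 h, 50 and 38 became 777 and 896 with the authors' calls. For the untreated libraries, 95 and 169 became 233 and 226 with a pseudocount of 0.1. No value moved without a filter, with FPKM of at least 5, with centring, or, for the untreated libraries, without heart muscle genes. Dropping the filter cannot change a count against a control, because a log2 change of 1 with a pseudocount of 1 needs an FPKM of at least 1. The libraries pair only by time. A fit with time as a block was not run, since it would average each cytokine's change over 1 h and 4 h and take the difference between these changes as error. Depth limits the low values more in the control of 4 h than in the treated libraries of 4 h, and read numbers are not known.

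With the control of the other time, higher and lower genes numbered 178 and 117 for IL-4 1 h, 128 and 152 for IL-4 4 h, and 433 and 345 for IL-33 1 h. This setting adds the difference between the untreated libraries by construction. The authors' calls used here were those per transcript, not those of their shorter gene list. With them the genes numbered 777 and 896 for IL-4 1 h, 930 and 713 for IL-4 4 h, 723 and 570 for IL-33 1 h, and 714 and 402 for IL-33 4 h. The calls in the authors' deposited table shared by both cytokines were 277 and 237 at 1 h and 234 and 139 at 4 h, and those at both times were 330 and 304 for IL-4 and 275 and 93 for IL-33. These calls carry no minimum size and are made per transcript, so a gene with transcripts marked in both directions (389 and 356 genes for IL-4, 103 and 52 for IL-33) counts as higher and as lower, and the cause of the larger counts was not tested further.

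With a pseudocount of 0.1, which gives low genes larger log2 changes, 118 genes were higher and 65 lower with IL-4 at 4 h, 127 lower with IL-33 at 1 h, 324 lower with IL-33 at 4 h, and 233 higher and 226 lower in untreated cells at 4 h. Genes lower with IL-33 than with IL-4 numbered 110 at 1 h and 290.0 at 4 h, those lower at both times with IL-33 26, and the correlations were 0.467 at 1 h and 0.498 at 4 h.

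Without small RNA genes, higher and lower genes numbered 10 and 2 for IL-4 1 h, and 32 and 1 for IL-4 4 h. With IL-33 at 1 h 30 were lower, and in untreated cells at 4 h 49 were higher. Genes shared by both cytokines were 2 and 1 at 1 h and 21 and 0 at 4 h. The correlations were 0.279 at 1 h and 0.264 at 4 h, genes lower with IL-33 than with IL-4 at 1 h numbered 33, and those at both times 3 higher and 0 lower for IL-4 and 7 lower for IL-33. These falls follow from the genes left out.

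With the highest transcript in place of the sum, 75 genes were lower with IL-4 at 1 h, 75 with IL-4 at 4 h and 11 with IL-4 at both times, and 160 were higher in untreated cells at 4 h. The cause was not tested. Without genes holding failed or low-data transcripts, the correlation at 4 h was 0.446, and the cause was not tested.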

Other observations

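The 8 tests of explanations below were chosen after the results they bear on had been seen, and the heart, skeletal muscle and liver genes were chosen after the data had been examined. Members of further gene lists went past the rule with IL-33. At 4 h, cholesterol synthesis and uptake genes had a median log2 change of 0.66 (percentile 100) with 3 of 23 members higher, among them the exporter gene Abca1 (3.05 to 10.2 FPKM) and Idi1 (49.3 to 113.6). At 1 h, 2 of 23 were higher, among them Insig1 (43.2 to 95.4). Lipid mediator genes went both ways at 4 h, with 3 of 22 higher, Ptgs2, the prostacyclin receptor gene Ptgir (5.51 to 22.1) and the prostaglandin E synthase gene Ptges (1.08 to 3.54), and 2 lower, the leukotriene receptor gene Ltb4r1 (157 to 66.4) and Ltc4s, and a list median of -0.18 (percentile 4.32, within the central 95% of random lists). Of 26 hypoxia and glycolysis genes 3 were higher at 4 h, Hif1a (45.6 to 114), Ankrd37 (1.65 to 5.80) and Egln3 (12.98 to 31.6), with a list median of -0.04 (percentile 26.2) that did not stand apart from random lists. In the IL-1 receptor pathway 2 of 25 members were higher at 4 h, the inhibitory kinase gene Irak3 (28.7 to 194) and Map3k8 (1.06 to 11.4).

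Of the interferon response genes, 3 of 34 were higher with IL-33 at 4 h, Cxcl10, Gbp2 (3.00 to 17.2) and Gbp3 (0.849 to 2.75), with a median of 0.02 (percentile 80.6), and at 1 h 3 of 33 were higher, Cxcl10, Gbp2 (4.42 to 11.8) and Irf5 (36.0 to 75.3), and 1 lower, Usp18 (44.9 to 19.9). None of 16 antigen presentation genes was past the rule, although B2m stood at 1385 FPKM in the control and 2279 with IL-33 at 4 h. Heat shock and unfolded protein genes had no member past the rule with either cytokine, but their median of 0.11 with IL-4 at 4 h stood at percentile 99.99. None of 19 housekeeping genes was past the rule in any comparison. Among 11 lymphoid markers, Ccl5 (15.3 to 55.3) and Klrb1c (1.85 to 7.07) were higher with IL-33 at 4 h, and among 9 erythroid and megakaryocyte markers the erythropoietin receptor gene Epor was lower (8.00 to 2.85). Of 87 named genes, 0 went past the rule in opposite directions between the times of a cytokine or between the cytokines at a time.

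Most heart muscle transcripts listed stood in all 3 libraries of 1 h and near 0 in those of 4 h, where the median residue in the control was 2.10% of the level at 1 h over all 29 and reached 77.9% for Slc25a4. The 13 heart genes seen first among the falls prompted the list and cannot test it. A further 20 heart and atrial genes were listed before their own values were seen. Of these, 15 were higher in each library of 1 h than in every library of 4 h. So were 2 of 10 fast skeletal muscle genes and 0 of 8 liver genes. The 2 were Myh4 and Myh1, at only 0.0250 and 0.0238 FPKM in the control of 1 h. Of the 4 atrial genes among the 20, only 1 was higher in this way. It was Nppa, with 50.8% of its level left in the control of 4 h. The pattern of the heart muscle genes is what RNA or reads of heart muscle mixed into the libraries of 1 h might give. Some members, such as Atp2a2 (29.7 FPKM in the control of 4 h), are also expressed without it. Over the 20 of the 29 heart muscle genes with FPKM of at least 1 in the control of 1 h and under 10% of that level left at 4 h, the log2 ratio to control 1 h had a median of -0.52 and an SD of 0.234 for IL-33 1 h and of -0.51 and 0.355 for IL-4 1 h, as a single heart source in all 3 libraries might give. A change of the cultured cells between 1 h and 4 h cannot be told apart from this, because time and library are the same split.

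The cytokine transcripts that rose with IL-33 stood in libraries that also held transcripts of other blood cells. A larger share of basophils or mast cells in the library of IL-33 4 h would raise their markers along with Il13, but the median log2 change of 10 markers was -0.16 (SD 0.693), below the bound of 2.30 set from the change of Il13 (4.60). Macrophage and neutrophil markers likewise had a median of -0.16 (44 genes, SD 0.700), below the bound of 3.17 set from Cxcl2. This argues against a larger share of those cells as the main source of the rise of Cxcl2. The bounds are wide and do not exclude a smaller increase in the share of any of these cells. Single markers were higher, 4 of 24 in the monocyte, macrophage and dendritic cell list and 1 of 20 in the neutrophil list, and none was lower. A response within a constant minority of other cells cannot be told apart from a response of eosinophils, since bulk libraries do not say which cell holds a transcript. Cpa3, a gene of mast cells and basophils, stood at 97.8 FPKM in the control of 4 h, so such cells could have contributed Il4 and Il13 transcripts.

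Of 32 genes higher with IL-4 at 4 h, 21 were also higher with IL-33 at 4 h and 3 with IL-33 at 1 h, but the first count shares its control with the choice of these genes and the second does not. Simulated unchanged libraries with a shared control had 31.8 or, with noise from IL-4 1 h, 2.44 genes in common. The value of 31.8 decides little, because the overlap could not be larger than the 32 genes higher with IL-4. The value of 2.44 rests on noise from libraries of 1 h near equal in depth. The control of 4 h was shallower than its partners, so noise shared through it may be larger. Against the control of 1 h, 13 of the 21 were past the rule with both cytokines of 4 h, and 15 with IL-33. For those 13, this argues against a low value in the shared control of 4 h as the whole cause, unless they rose with time in culture. The control of 1 h stands in a separately normalised table and adds the difference between the untreated libraries. IL-4 released by the cells acting between 1 h and 4 h is a hypothesis in the title of the series. It may account for some of the 21 genes, but the data do not decide it. Of 10 genes higher with IL-4 at 1 h, 4 were higher with IL-33 at 4 h and 2 at 1 h. Without the small RNA genes, 396 of 10653 genes were higher with IL-33 at 4 h and 207 of 10478 at 1 h. The count of 2 shares the control of 1 h with the choice of the 10 genes, and the count of 4 does not. Of these 10 genes, Ccl2 stood just under the rule with IL-33 at 1 h (0.97). An action of released IL-4 cannot be told apart from a direct action of IL-33. No library with IL-4 blocked was analysed here, and NF-kB can raise some of the same genes.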
